A study of Homo sapiens with 2 samples.

How the data were processed

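Both libraries were deposited as matrices of raw UMI counts per gene symbol and cell barcode, 1 for RUES2 and 1 for the isogenic line with 56 CAG repeats in HTT (56CAG). Per the labels' protocols, colonies on 500 µm micropatterns were treated with the TGF-beta receptor inhibitor SB431542 (10 µM), first with the BMP receptor inhibitor LDN193189 (0.2 µM) and then with BMP4 (3 ng/mL), and were dissociated with Accutase on day 7. Both suspensions were captured separately with 10x Genomics Single Cell 3' v2 reagents. The submitters' processing notes name the genome build hg19, Cell Ranger 2.0.2, R 3.5.1 and Seurat 2.3.4 for the deposited counts; the settings used are not given in the sources used here. In each file every listed gene was seen in at least 3 cells; 794 genes were listed for RUES2 only, 919 for 56CAG only and 19009 for both. A gene not listed for a library was counted as 0 there. The lowest depth of a cell was 5472 UMIs in RUES2 and 5412 UMIs in 56CAG.

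Cells with fewer than 500 genes or with 10% or more of UMIs from mitochondrial genes were left out (0 and 3 cells). Scrublet, run through scanpy 1.11.5 on each library with an expected doublet share of 6%, called 4 RUES2 cells and 0 56CAG cells, 0.0602% of all; the caller did not work on these data, so that doublets remain in the analysis. With its calls removed, 2622 RUES2 and 4021 56CAG cells were used. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were standardized (capped at 10), and 30 principal components gave a graph of 15 nearest neighbours weighted by shared neighbours. Both libraries were clustered together with no batch correction (leidenalg 0.10.2, resolution 0.8, seed 1; Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9). Cells of unnamed clusters with markers of more than 1 lineage were clustered again without cell cycle genes, which gave 16 clusters in all.

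Marker genes of 13 cell types were fixed before the data were examined, as were the filters, the clustering settings, 34 gene lists and the rule for named genes. A cluster's score for a type was the mean, over markers of at least 30 CPM and 3-fold contrast between clusters, of its level relative to the highest level in any cluster of at least 50 cells. A cluster took the name of its best type at a score of at least 0.4 with at least 3 markers at 0.5 of their highest level or above, if every rival among neural epithelium, neural crest, neuron and epidermis scored at most 0.2 or lay at least 0.4 lower; other types, such as amnion, did not count as rivals. These thresholds were set after the clusters were seen and were revised 2 times; both earlier rules are among the alternatives. Clusters with at least 5 of their 10 leading genes in a set that includes PTPRS and CTNNB1, chosen after the data were seen, stayed unnamed. Of the 10 named clusters, 1 had more markers of another type than of its own among its 10 leading genes by fold against all other cells, and 0 had against cells outside its class, which was the rule used to allow the comparison of classes. Ties passed this rule, such as 0 own and 0 other markers in the crest-like cluster led by HIST1H1B. The crest-like cluster led by ACTC1 passed with 1 own and 1 other marker. Passing thus does not by itself support a name. A per-cell value of that transcript set, the UMIs of 10 of its genes per 10000, was called high above 8; 228 RUES2 cells and 379 56CAG cells lay within 2 of that limit.

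Deposited counts were summed per library over all cells and within each named class of at least 100 cells in both libraries, and CPM was computed from these sums. The log2 ratio of CPM, 56CAG over RUES2, was given an exact conditional 95% interval for the ratio of Poisson counts, CPM an exact Poisson interval and shares an exact Clopper-Pearson interval; all of them cover counting error only. Counts of 0 were set to a floor of 3 for ranking. With 1 library per line there was no test across replicates, and no p-value was computed. The genes named were chosen among the 10 with the highest and the 10 with the lowest ratio among genes of at least 50 CPM in 1 library, HTT, list members of at least 50 CPM with a log2 ratio of at least 1 in size (at most 4 per list), and the markers of a class. Unnamed clones, XIST, TSIX and Y-linked genes were left out of the ranking. XIST, TSIX and Y-linked genes were also left out of the medians of all genes, lists and chromosomes. Some genes, clusters and values that depend on them are not reported here. Other list members and cluster genes printed were chosen as examples after their values were seen. A list's median over members of at least 10 CPM was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries, and lists with fewer than 5 such members were not evaluated. Chromosomes and neighbouring genes were taken by symbol from RefSeq for GRCh38.p14, another build than that of the files, so no coordinates are given; 8205 of 8337 genes (98.4%) matched. Shares of cells with a UMI were compared after each cell was thinned to 5400 UMIs.

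The steps were tested on simulated counts for 56CAG against RUES2, drawn as Poisson counts around the RUES2 mean levels. Set library totals, smaller than the real ones, were used, and 8246 genes were evaluated. Since the simulation and the intervals share the Poisson model, coverage near 95% checks the computation and not the spread between captures. The intervals held the true value for 95% of 100 genes changed by a log2 ratio of 1, 90% of 100 genes changed by 2 and 95.4% of 8046 unchanged genes. All 20 genes named there carried the larger change, and 1 of 60 unchanged lists fell outside the central 95% of random lists. The alternatives varied the cell filter, doublet removal, clustering, class names, scaling, depth, expression minimum and random lists; how the results depend on them is described after the results. Plots were drawn with matplotlib 3.10.9.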

Results

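The data are UMI counts per gene and cell from neuruloids, self-organized colonies of human embryonic stem cells that form the ectodermal tissues of the early embryo. Colonies of 500 µm diameter were grown with 3 ng/mL BMP4 and collected on day 7. They came from RUES2, an established human embryonic stem cell line, and from an isogenic RUES2 line labelled with 56 CAG repeats in HTT, the gene whose CAG expansion causes Huntington disease (56CAG below). Each line gave 1 droplet library, so no difference has a replicate check, no test was run and every interval covers counting error only. The RUES2 library held 2626 cells and 43373134 UMIs, with a median of 13368 UMIs and 3667 genes per cell. The 56CAG library held 4024 cells and 55051472 UMIs, with a median of 10547 UMIs and 2910 genes. After every cell was thinned to 5400 UMIs, which left out 0 cells, the median was 2052.5 genes in RUES2 and 1871 in 56CAG.

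The first comparison asked which ectodermal cell types each line formed. Neural epithelium-like cells, marked by PAX6 and OTX2, transcription factors of the anterior neural plate, and by CDH2, the neural cadherin, made up 43.7% of RUES2 cells (1147 of 2622; exact 95% binomial interval 41.8 to 45.7%) and 17.2% of 56CAG cells (690 of 4021; 16.0 to 18.4%). The share was 2.55-fold lower in 56CAG. The largest cluster of this class (517 RUES2 and 313 56CAG cells) had 0 markers of neural epithelium among its 10 leading genes. It scored 0.554 for that type, against 0.991 for the cluster with PAX6, OTX2 and CDH2 among its leading genes. Neural crest-like cells, marked by SOX10 and TFAP2B, transcription factors of the migratory crest, made up 37.1% of RUES2 cells (35.3 to 39.0%) and 41.1% of 56CAG cells (39.6 to 42.6%). Epidermis-like cells, marked by the simple-epithelium keratins KRT8, KRT18 and KRT19, made up 4.65% (3.88 to 5.53%) and 3.06% (2.55 to 3.64%), and neuron-like cells, marked by STMN2 and ELAVL3, 1.91% (1.42 to 2.51%) and 1.14% (0.839 to 1.52%). With each cell named by its own markers these last 2 shares were higher in 56CAG, at 5.30 and 7.61% for epidermis-like cells and 4.08 and 6.42% for neuron-like cells. Among cells in a named class only, neural epithelium-like cells were 50.0% in RUES2 and 27.5% in 56CAG, and neural crest-like cells 42.5% and 65.8%.

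**Figure D1:**
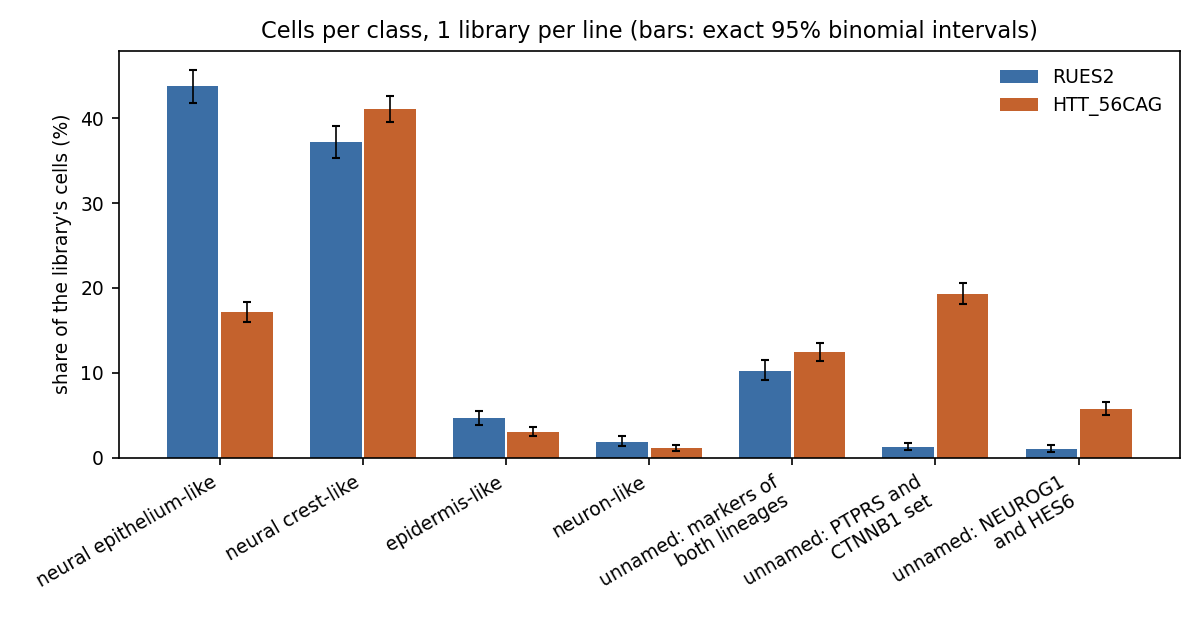
Share of each library's cells (%) in the 4 named classes and in the 3 sets of unnamed clusters, with RUES2 and 56CAG side by side and exact 95% binomial intervals as error bars. Neural epithelium-like cells stand at 43.7% in RUES2 and 17.2% in 56CAG, and the unnamed clusters led by PTPRS and CTNNB1 at 1.26% and 19.3%.

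Unnamed clusters held 12.5% of RUES2 cells and 37.5% of 56CAG cells, under naming thresholds set after the clusters were seen. Of these, 2 clusters led by PTPRS, a receptor tyrosine phosphatase, and CTNNB1, which encodes beta-catenin, held 1.26% of RUES2 cells (0.868 to 1.76%) and 19.3% of 56CAG cells (18.1 to 20.6%). When these 2 clusters took the lineage with the higher marker score, the log2 ratio of the neural epithelium-like share, 56CAG over RUES2, went from -1.35 to -0.74 and that of the neural crest-like share from 0.15 to 0.44. Another 3 clusters with markers of both lineages held 10.3% and 12.4%: one led by POU4F1, a factor of sensory neurons (8 RUES2 cells, 354 56CAG cells), one by HES5, a Notch effector of neural progenitors (162 and 5), and one by the proliferation gene MKI67 (99 and 141). POU4F1 was at 177 CPM in the cluster it led and at 241 CPM in 56CAG neural epithelium-like cells. HES5 was at 42.9 CPM in the cluster it led and at 40.8 CPM in RUES2 neural epithelium-like cells. Neither gene thus sets its cluster apart from the neural epithelium-like cells of the library that holds most of it. The median depth of neural epithelium-like cells was 11663 UMIs in RUES2 and 8990 in 56CAG, and that of neural crest-like cells 14052.5 and 10699.

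The clusters of the crest-like class differed in share between the libraries. A cluster led by PRSS56 and MITF, the transcription factor of the melanocyte lineage, held 17.3% of RUES2 cells (453) and 0.249% of 56CAG cells (10). MITF was at 78.8 CPM in this cluster and 76.8 CPM over all RUES2 crest-like cells, so it does not set the cluster apart within RUES2. LY6E, a gene not listed for 56CAG, was also among its 10 leading genes. Another cluster held 34 RUES2 cells and 840 56CAG cells. The log2 ratio of the crest-like share was 0.15 with all clusters, 1.04 without the PRSS56-led cluster, -0.83 without the cluster held mostly by 56CAG and 0.10 without both. Leaving out either cluster alone takes cells mainly from 1 library, so the directions of 1.04 and -0.83 were set in advance. The direction of the share thus depends on which clusters are counted. The design does not separate such clusters from a difference between the captures. Clusters led by mitotic genes such as CDC20 held 5.61% and 8.01%, by replication histones such as HIST1H1B 6.71% and 7.01%, and by ACTC1 and the replication genes MCM4 and PCNA 6.25% and 4.95%. The cardiac actin ACTC1, a muscle marker, led its cluster when it was set against all other cells, with no crest marker among the 10 leading genes; without that cluster the log2 ratio of the crest-like share was 0.23.

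A further cluster was led by HES6 and NEUROG1, a helix-loop-helix factor that starts sensory neurogenesis, with NHLH1, another neurogenic factor. It held 27 RUES2 cells (1.03%; 0.680 to 1.49%) and 233 56CAG cells (5.79%; 5.09 to 6.56%), a log2 ratio of 2.49. It expressed TFAP2B at 658 and 620 CPM in RUES2 and 56CAG. At 5400 UMIs per cell, NEUROG1 was seen in 5.87% of RUES2 cells and 15.2% of 56CAG cells (11.1 and 24.5% without thinning). Within the neural crest-like class it was seen in 6.88% (5.37 to 8.65%) and 13.1% (11.5 to 14.8%), against 0.697% and 2.32% in the neural epithelium-like class, which stands as the background. At the same depth HES6, the other leading gene, was seen in 5.85% (4.46 to 7.52%) and 5.63% (4.56 to 6.85%) of neural crest-like cells.

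The second comparison asked which genes differed in level between the lines. HTT itself was measured at 21.9 CPM in RUES2 (20.5 to 23.3) and 15.8 CPM in 56CAG (14.7 to 16.8) over all cells, a log2 ratio of -0.47 (-0.61 to -0.34). It was -0.57 in neural epithelium-like cells, -0.38 in neural crest-like cells and -0.10 (-0.74 to 0.54) in epidermis-like cells. The 3' reads lie far from the CAG repeat at the start of the gene, so HTT counts check nothing about the edit. The median log2 ratio of all 8337 genes of at least 10 CPM was -0.19, a shift of untested cause that the ratios over all cells include; relative to it HTT stood at -0.29.

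Over all cells, the genes with the highest ratios in 56CAG included NEUROG1, at 21.3 CPM in RUES2 and 52.5 CPM in 56CAG (log2 ratio 1.30), PTPRS (1.22) and the long noncoding RNA LINC01021 (41.8 and 89.4 CPM). ZNF883, FAM162A, ZNF677, MT1X, a metallothionein, and GYPC, a membrane sialoglycoprotein (0.77), were also among the highest genes. Lowest among genes of at least 50 CPM in 1 library and listed for both was CD81, a tetraspanin, at 101 and 21.2 CPM (-2.26, -2.35 to -2.17). FHL1, a LIM-domain protein of muscle, stood at -1.82, NOS2, the inducible nitric oxide synthase, at -1.73, TAGLN, an actin-binding protein, at -1.52, MID1 at -1.49, CCDC160 at -1.49, CAMK2N1, an inhibitor of calcium/calmodulin kinase, at -1.43 and RSPO3, a secreted Wnt agonist, at -1.42. The imprinted gene NNAT (93.6 CPM in RUES2) and LY6E (80.3 CPM) were not among the genes listed for 56CAG; since each file lists only genes seen in at least 3 cells, no fold is given for them. PTPRS is a gene of the unnamed clusters described above, and NOS2, RSPO3, OTX1 and OTX2 (-1.01 each for the last 2) are expressed in neural epithelium, whose share was lower; within neural epithelium-like cells NOS2 was at -1.01, RSPO3 at -0.71, OTX1 at -0.40 and OTX2 at -0.27.

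Within neural epithelium-like cells, CD81 was at 95.5 CPM in RUES2 and 17.2 CPM in 56CAG (-2.47, -2.75 to -2.21) and COLEC12, a scavenger receptor, at 78.1 and 19.2 CPM (-2.03). FHL1 (-1.58), the membrane proteolipid GPM6B (-1.45), the actin regulator EVL (-1.45), CCDC160 (-1.42), CAMK2N1 (-1.30) and MID1 (-1.22) completed the lowest genes with NNAT and LY6E. BMP4, the ligand added to the cultures, was at 53.2 and 24.3 CPM (-1.13), and XIAP, an inhibitor of caspases, at -1.10. The highest genes included MT1X (1.15, 0.98 to 1.32), ZNF883 (1.14), the histone gene HIST1H2BD (1.07), POU4F1 (124 and 241 CPM, 0.96), ZNF677 (0.94), LINC01021 (0.89), HIST1H2AC (0.88), PKIB (0.83) and MSMO1, a sterol synthesis enzyme (0.76). The crest gene TFAP2B had low counts in these cells that were higher in 56CAG, at 18.9 and 47.9 CPM, against 461 and 473 CPM in the crest-like class. POU4F1 went to -0.17 when each library was clustered on its own; the median ratio of all genes in this class was -0.14.

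Within neural crest-like cells, CD81 was again low, at 94.1 and 19.5 CPM (-2.27). MITF, the melanocyte factor, was at 76.8 and 29.2 CPM (-1.40, -1.54 to -1.25), followed by FHL1 (-1.29), the Dishevelled-binding protein DACT1 (-1.26), the electron transfer flavoprotein subunit ETFA (-1.23), ID4, a BMP-responsive inhibitor of differentiation factors (-1.23), CCDC160 (-1.21) and TAGLN (-1.19), besides LY6E and NNAT. TMSB4X, an actin-sequestering peptide and among the most abundant transcripts of the cells, was at 7767 and 3457 CPM (-1.17), and MYL9, a myosin regulatory light chain, at 80.2 and 35.9 CPM (-1.16). The highest genes included LINC01021 (25.7 and 59.1 CPM), FAM162A, a mitochondrial protein induced by hypoxia (153 and 321 CPM, 1.07), IGFBP5, an insulin-like growth factor binding protein (0.99), ZNF883 (0.93), MT1X (0.86), P4HA1, a collagen prolyl hydroxylase (0.84), PKIB (0.80), the LIM protein CSRP2 (0.77) and HLA-B (0.77). The PRSS56-led cluster made up 453 of the 974 RUES2 cells of this class and 10 of the 1653 56CAG cells. Without that cluster, without the cluster held mostly by 56CAG, or without both, all 20 genes at the ends of the ranking kept their side of 0. They were picked for extreme ratios in the same counts, so this is a weak check.

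**Figure D2:**
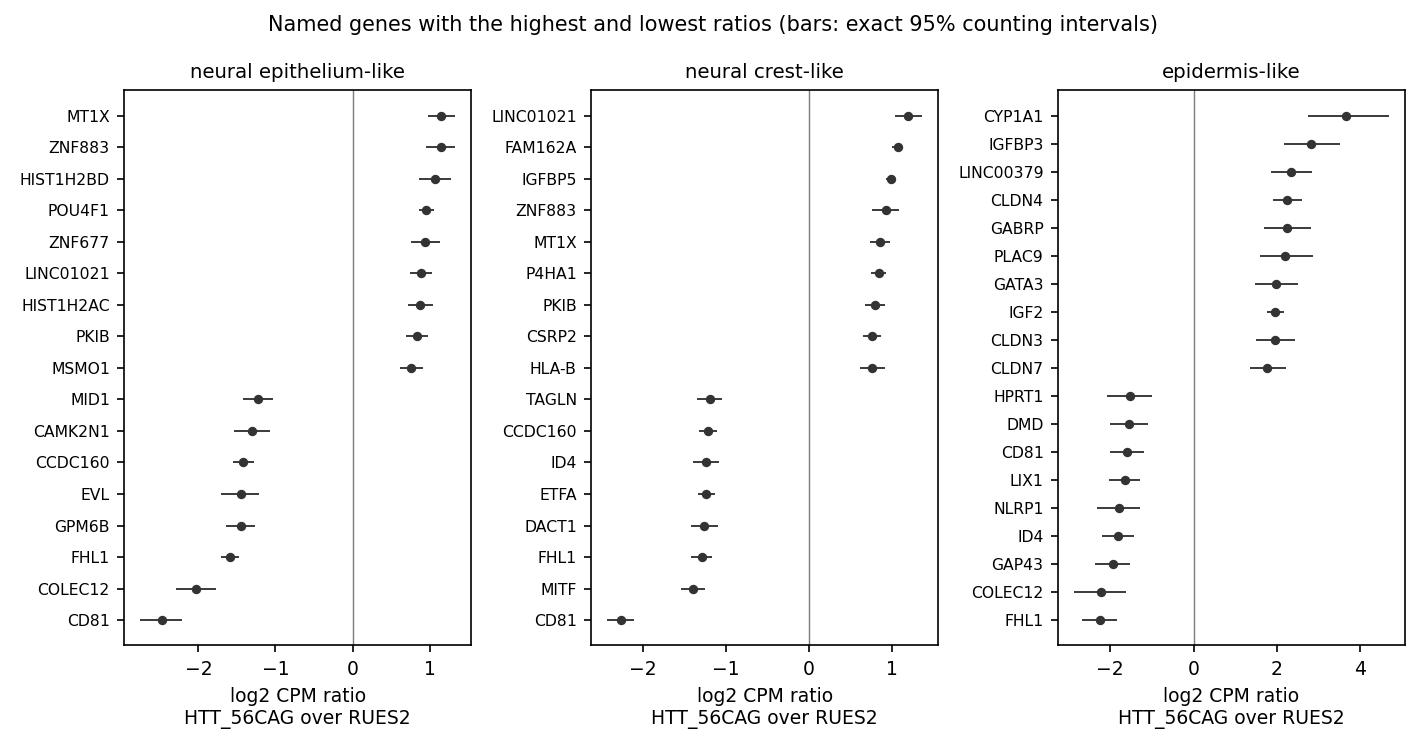
Log2 CPM ratio, 56CAG over RUES2, of genes reported among the highest and lowest and listed for both libraries in 3 classes, with exact 95% counting intervals as bars and 1 library per line. CD81 lies at -2.47 in neural epithelium-like cells, -2.27 in neural crest-like cells and -1.59 in epidermis-like cells, and CLDN4 at 2.25 in epidermis-like cells.

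Epidermis-like cells, a single cluster of 122 RUES2 and 123 56CAG cells, had higher epithelial junction genes in 56CAG. The claudins CLDN4 (35.9 and 170 CPM; log2 ratio 2.25, 1.91 to 2.60), CLDN3 (1.95) and CLDN7 (1.77), the epithelial cadherin CDH1 (1.34) and the adhesion molecule EPCAM (1.49) stood with CYP1A1, a target of the aryl hydrocarbon receptor (3.65, 2.75 to 4.69), IGFBP3 (2.81), LINC00379 (2.34), GABRP (2.24), PLAC9 (2.21), GATA3, a factor of surface ectoderm and trophoblast (1.98), and the growth factor IGF2 (1.96). KRT19 was at 232 CPM in RUES2 and 698 CPM in 56CAG. Several mesenchymal genes were lower: VIM, which encodes vimentin, at 3013 and 1418 CPM (-1.09), SNAI2 (-1.35), MSX1 (-1.31), TWIST1 at 46.9 and 10.5 CPM (-2.15) and PRRX1 at 49.3 and 13.5 CPM. The collagen genes COL1A1 (61.1 and 36.1 CPM) and COL3A1 (32.6 and 13.0 CPM) were lower too. COL1A2 differed less, at 318 and 279 CPM, and ALX1 was not lower, at 9.37 and 14.0 CPM. Also low were FHL1 (-2.23), COLEC12 (-2.22), the growth cone protein GAP43 (-1.93), ID4 (-1.81), the inflammasome sensor NLRP1 (-1.78), LIX1 (-1.65), CD81 (-1.59), DMD, which encodes dystrophin (-1.54), and HPRT1, an enzyme of purine salvage (-1.52). This cluster scored 0.965 for epidermis and 0.930 for amnion or trophoblast, and of the amnion markers GABRP (14.7 and 69.2 CPM), IGFBP3 (9.78 and 68.7 CPM) and TFAP2C (48.9 and 71.2 CPM) were higher in 56CAG while HAND1 was at 32.6 and 30.6 CPM, so that its make-up of epidermal, mesenchymal and amnion-like cells was not resolved.

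Lists of genes of a pathway or structure were compared by their median log2 ratio minus that of all genes in the class. The planar cell polarity list (Frizzled, Vangl and their partners), which orients cells in an epithelium, lay near the other genes: -0.07 over 16 measured members in neural epithelium-like cells, percentile 17.8 among random lists matched on expression, and 0.01 over 14 members in neural crest-like cells, percentile 59.3. The core receptor gene FZD3 was at 390 and 367 CPM in neural epithelium-like cells, while the log2 ratio of the Wnt co-receptor RYK was -0.90. The actomyosin list was lower than other genes in neural crest-like cells, at -0.19 over 45 members (-0.25 to -0.13 over 22 alternatives) with 10 of them above the median of all genes, percentile 0. There TMSB4X, MYL9 and TAGLN were joined by ACTB, the cytoplasmic actin, at 2091 and 1255 CPM (-0.74), while CALD1, caldesmon, stood at 0.30. In neural epithelium-like cells the actomyosin list was at -0.04, with 20 of 45 members above the median of all genes, percentile 0.405 among matched and 16.6 among unmatched random lists. The apical junction list was at -0.06 in neural epithelium-like and -0.10 in neural crest-like cells, percentiles 20.3 and 9.51, and at 0.63 in epidermis-like cells, percentile 100, where 21 of 24 members lay above all genes.

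Targets of canonical Wnt signalling were lower than other genes in each of the 3 classes: -0.45 in neural epithelium-like cells (7 members, percentile 0.03), -0.34 in neural crest-like cells (8 members, percentile 0.17) and -0.35 in epidermis-like cells (12 members, percentile 0.68). LEF1, a nuclear partner of beta-catenin, was at 28.3 and 16.5 CPM in neural epithelium-like cells, and AXIN2, a feedback inhibitor of the pathway, at 62.4 and 41.3 CPM. In neural epithelium-like cells 0 of the 7 members, in neural crest-like cells 0 of the 8 and in epidermis-like cells 4 of the 12 lay above the median of all genes. BMP targets were at -0.17 in neural epithelium-like cells (percentile 1.38), -0.22 in neural crest-like cells (percentile 0.64) and -0.23 in epidermis-like cells (percentile 0.605), with ID4 and MSX1 lower in each. In neural crest-like cells the value became 0.068 without the cluster held mostly by 56CAG and 0.080 without both clusters held mostly by 1 library. The epidermis-like members were divided: GATA3 (1.98) and DLX5 (1.06) were higher in 56CAG, and 6 of 15 lay above the median of all genes. Above that median lay 3 of 10 members in neural epithelium-like cells and 1 of 8 in neural crest-like cells. The Notch list was higher than other genes in neural epithelium-like cells (0.30, percentile 99.98) with HES4 at 93.8 and 141 CPM, but HES5 was at 40.8 and 10.4 CPM (-1.98). The G2/M list was at -0.49 in neural epithelium-like cells (1 of 52 members above all genes) and 0.0080 in neural crest-like cells. In neural epithelium-like cells it became 0.044 under the naming rule first tried. In neural crest-like cells it became -0.57 without the PRSS56-led cluster and 0.65 without the cluster held mostly by 56CAG, removals that each take cells mainly from 1 library.

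**Figure D3:**
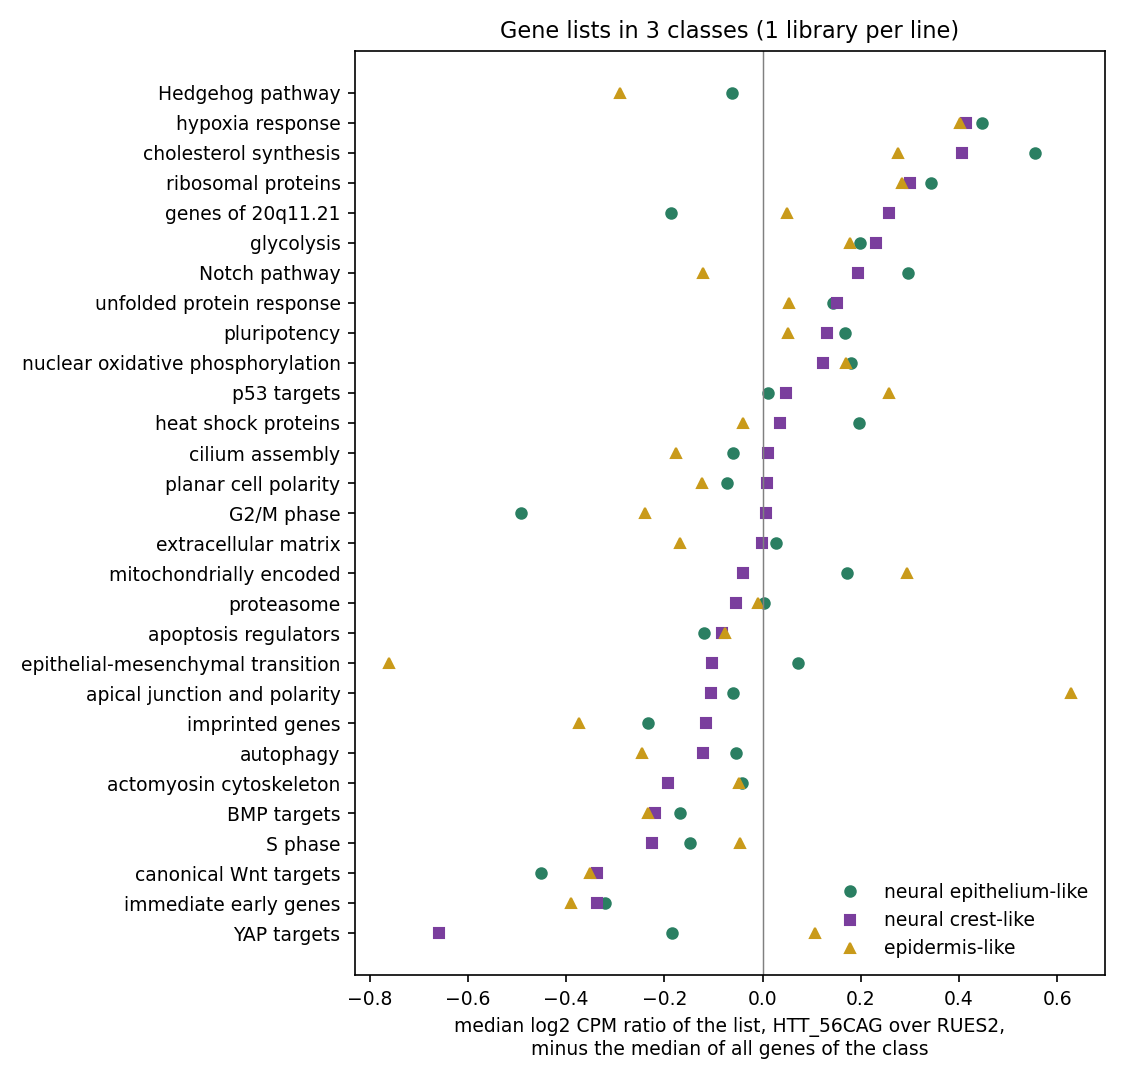
Median log2 CPM ratio of each gene list, 56CAG over RUES2, minus the median of all genes of the same class, in neural epithelium-like (circles), neural crest-like (squares) and epidermis-like cells (triangles), from 1 library per line, without lists measured in fewer than 2 classes. Canonical Wnt targets lie at -0.45, -0.34 and -0.35 and the apical junction list at 0.63 in epidermis-like cells.

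The last comparison asked whether the lines differed by a gained or lost chromosome. Over all cells the autosomal medians lay within 0.06 (log2) of all genes. Chromosome 12, with 443 genes, lay furthest, at -0.06 (percentile 0), and chromosome 19, with 543 genes, at 0.05 (percentile 100). The list of genes of 20q11.21, a band often gained in human embryonic stem cell cultures, was at 0.00 over all cells (10 members, percentile 46.0), -0.19 in neural epithelium-like cells (percentile 0.8) and 0.26 in neural crest-like cells (percentile 99.9). A gain held by a small share of the cells is not detectable in medians of this kind.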

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

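The alternatives that left out or named the PTPRS and CTNNB1 transcript-set cells, used other naming rules or shares of named cells, or left out neural crest-like clusters were tests chosen after the data were seen. The neural epithelium-like share was lower in 56CAG under all 17 alternatives (log2 ratio -2.50 to -0.74), and the NEUROG1-led share higher under all 15 (1.78 to 2.66). The neural crest-like share ranged from -0.83 to 1.04 over 21 alternatives. Separate clustering formed no neuron-like class in both libraries and gives no value there.

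Neural epithelium-like shares moved to -1.06 with genes scaled within each library (the NEUROG1-led share to 1.78), -2.50 with separate clustering, -1.03 with each cell named by its own markers, -1.02 without transcript-set cells, -2.06 under the naming rule first tried, -0.74 with transcript-set clusters named and -0.86 among named cells. Neural crest-like shares moved to 0.47 without transcript-set cells, 0.44 with their clusters named, 0.63 among named cells and 1.04 without the PRSS56-led cluster, and reversed to -0.83 without the cluster held mostly by 56CAG, since each removal takes cells mainly from 1 library. With each cell named by its own markers, the epidermis-like and neuron-like shares reversed to 0.52 and 0.65; among named cells the epidermis-like value was -0.12. For the other values the cause was not tested.

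The 20 genes at the ends of each ranking stayed on their side of 0 under every alternative run for genes (naming each cell by its own markers and leaving library-different genes out were run for shares only), except that POU4F1 in neural epithelium-like cells reversed to -0.17 under separate clustering (19 of 20; the cause was not tested). The genes of each ranking were picked for extreme ratios in the same counts, so keeping their side of 0 was largely set in advance. At a minimum of 20 CPM, 7, 7, 9 and 3 of the 20 were still named (all cells, neural epithelium-like, neural crest-like, epidermis-like), and at 200 CPM 1, 3, 2 and 1, since the minimum decides which genes are ranked. Of 2108 gene values, 1734 kept within the counting interval.

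Without the PRSS56-led cluster the actomyosin list in neural crest-like cells went to -0.25. Without the cluster held mostly by 56CAG it went to -0.13, BMP targets there to 0.068, the mitochondrially encoded list to 0.028 and S phase to 0.25; without both, planar cell polarity went to -0.080, BMP targets to 0.080 and the mitochondrially encoded list to 0.0016. Under the naming rule first tried, neural epithelium-like values were 0.0091 (actomyosin), 0.030 (S phase) and 0.044 (G2/M). With transcript-set clusters named, S phase there was 0.12, and in neural crest-like cells the mitochondrially encoded list was 0.0084 and the proteasome list 0.0020. G2/M in epidermis-like cells went to 0.039 with fewer and 0.037 with more variable genes and components, 0.068 with scaling within each library and 0.36 with separate clustering. Apical junction genes in neural crest-like cells went to 0.024 with members of 2 CPM, and the proteasome list over all cells to -0.020 with members of 50 CPM and -0.049 without transcript-set cells. Of 2165 list values 195 moved and 17 reversed, and of 116 list percentiles 26 moved with unmatched random lists; the cause was not tested.

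No paired analysis was possible because each line had 1 library. Depth limits shares of cells with a UMI, which were compared at 5400 UMIs.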

Other observations

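The tests of a separate cell type, of runs of A and of too few UMIs were chosen only after the results were seen, as were the X chromosome and the PTPRS-led set itself. Genes of cholesterol synthesis were higher than other genes in 56CAG in neural epithelium-like cells (0.55, 16 of 18 members above all genes) and neural crest-like cells (0.41, 17 of 18). In epidermis-like cells the list stood at 0.28 (14 of 19), but the counting intervals of all 19 members held 0. Hypoxia response genes, which include P4HA1, stood at 0.45, 0.42 and 0.40, glycolysis genes at 0.20, 0.23 and 0.18, and ribosomal protein genes at 0.34, 0.30 and 0.28 (56, 55 and 56 of 57 members above all genes). Random lists matched on expression also lay above all genes for the last 2 lists. Before the median of all genes (-0.14, -0.11 and -0.13) was subtracted, ribosomal protein genes stood at 0.20, 0.19 and 0.15. Their matched random lists stood at 0.0017, 0.0070 and 0.017 (percentiles 100, 100 and 99.92). On that scale glycolysis genes were at 0.056, 0.12 and 0.050, against -0.081, -0.065 and -0.063 (percentiles 99.16, 99.935 and 90.01). The excess over matched genes was thus smaller. Immediate early genes such as JUN, which respond to dissociation as well as to signals, stood at -0.32, -0.34 and -0.39, and imprinted genes at -0.23, -0.11 and -0.37 (percentiles 0.245, 6.31 and 0.05). YAP targets were at -0.19 in neural epithelium-like cells (8 members, percentile 7.43), -0.66 in neural crest-like cells (5 members, percentile 0.02) and 0.11 in epidermis-like cells (10 members, percentile 81). Epithelial-mesenchymal transition genes were at -0.76 in epidermis-like cells. Genes of the X chromosome had a median of -0.05 relative to all genes over all cells (317 genes, percentile 0.04). Within classes it was -0.053 in neural epithelium-like cells (percentile 0.02) and -0.047 in neural crest-like cells (percentile 0.03). In epidermis-like cells it was -0.13 (percentile 0). Several genes named above as lower in 56CAG are X-linked: FHL1, CCDC160, MID1, GPM6B, XIAP, TMSB4X, HPRT1 and DMD. A median over the chromosome does not show such single genes, and the cause of either was not tested.

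More 56CAG cells than RUES2 cells were high in the set of PTPRS, CTNNB1, HNRNPH1, MDM4 and 6 other transcripts: 32.6% against 14.5%. Fewer UMIs per cell in 56CAG were argued against as the whole cause, since over 6 ranges of UMIs per cell the median ratio of the shares was 2.21. That median gives each range the same weight. The shares were 66.7% in RUES2 and 69.5% in 56CAG at 5000 to 7000 UMIs, but 8.81% and 26.4% at 11000 to 14000. The ratio was 0.941 at 7000 to 9000 UMIs and 1.42 at 9000 to 11000, and 3.00 to 3.78 from 11000 UMIs on. In both libraries the share was highest at the lowest depth, so depth may account for part of the excess. A separate cell type stays open: high cells were at least 10.6% of each named class, but clusters of high cells were left unnamed by rule, and the shares were close in neural epithelium-like cells (10.6 and 11.4%) and neural crest-like cells (14.3 and 15.7%) but not in epidermis-like cells (18.9 and 35.8%), with most of the excess in unnamed cells (24.9 and 60.8%). Priming inside transcripts at runs of A stays open: 23.8% of 21 genes of the set had an inner run, 0.781 times the share of matched genes (interval 0.270 to 1.55), in a set widened after a first one held 2 genes. A state of the cells that differs between the lines, or a difference between the captures, may also underlie the set, and neither was tested.

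The 3 clusters with markers of both lineages may be 2 cells in 1 droplet. The test counted genes of at least 50 CPM more than 2-fold above every other cluster of the same library, and it gave 0 for the POU4F1-led cluster and 0 for the MKI67-led cluster, each in 56CAG cells only, and 0 for the HES5-led cluster in RUES2 cells only. The median UMIs of these cells were 1.01, 1.43 and 0.967 times the sum of the medians of the neural epithelium-like and neural crest-like classes, and the median Scrublet scores of the whole clusters were 0.141, 0.183 and 0.183, against 0.117 or lower in the other clusters. Their 10.3% of RUES2 cells and 12.4% of 56CAG cells exceed the 6% of doublets given to Scrublet, so that cells between the lineages stay open as well. No biological explanation was tested.

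Of genes of at least 10 CPM in RUES2, NNAT (93.6 CPM), LY6E (80.3 CPM), PUS7L (36.7 CPM), ZNF248 (21.3 CPM) and MIR4458HG (11.4 CPM) were not listed for 56CAG. Too few UMIs in 56CAG were argued against by the counts: at their RUES2 levels 626 UMIs (MIR4458HG) to 5150 UMIs (NNAT) would be expected there, and none of the 5 was seen in the 3 cells needed for listing. A large loss of the chromosome part that holds the gene was argued against by 49 measured neighbours with a median log2 ratio of -0.24 (medians per gene -0.30 to -0.15). The neighbours leave out genes not listed for 56CAG, such as LY6H, so a focal loss stays open. Silencing of these genes in the 56CAG line is a possible explanation that was not tested.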
